A study of Homo sapiens with 6 samples.

How the data were processed

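RNA of K562 cells, a human line from a chronic myeloid leukaemia in blast crisis that carries the BCR-ABL fusion, was measured on 6 NimbleGen arrays in 1 colour (Cy3). Per the labels, 3 samples came from cells given a lentiviral shRNA against BCR-ABL and 3 from cells given one against luciferase, a firefly enzyme with no human counterpart, as the control. The labels describe the 3 samples of each group as independent groups of cells. Groups were taken from the labels of each sample, and the replicate number from its title. The titles also carry codes that the labels do not explain, lnc3 for the luciferase samples and a numeric code for the BCR-ABL shRNA samples, so what the control received rests on the labels alone.

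The deposited values are intensities on a linear scale, 1 per array entry and sample, made with RMA per the submitters' processing notes. RMA corrects the background, normalizes the arrays to a shared distribution and summarizes the probes of an entry. Its version and settings, the array design and its genome build are not given in the sources used here. The number of probes behind an entry, a value of another kind that the authors deposited beside the intensity, was 3 for most entries and 1 for 13802 of 49387. Because RMA gives the arrays nearly the same distribution, a change shared by most transcripts would be removed from these values. The 25% quantile of log2 intensity lay between 5.07 and 5.12 on the 6 arrays, and the median between 6.28 and 6.34.

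Negative controls and repeated control entries were left out of the tests, which leaves 49387 entries. Of these, 20447 carry a RefSeq mRNA accession, 18534 a name beginning with ASLNC, 8386 another accession, 1495 an exon name, 311 a genomic interval and 214 a name beginning with HMlincRNA. RefSeq accessions were matched, without versions, to current symbols in a table of assembly GRCh38.p14, used for names alone. This named 19622 entries of 15696 genes and left 825 RefSeq entries without a name. The other classes are not paired with gene names here, so the non-coding transcripts on the array are reported as counts.

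The log2 of each deposited intensity was taken with no pseudocount and no further normalization. A linear model with empirical Bayes moderation (limma 3.58.1 in R 4.3.3) compared the 3 BCR-ABL shRNA samples with the 3 luciferase shRNA samples, two-sided, with Benjamini-Hochberg adjustment over all entries and a threshold of 0.05. Log2 changes are BCR-ABL shRNA minus luciferase shRNA. Gene lists (35) were fixed before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, on the entry of each gene with the highest mean, where at least 5 members were measured. The list of long non-coding RNAs had 0 measured members and was not tested, which leaves 34. Beside each list stands the number of members past the threshold over all entries, and the number adjusted over the list alone.

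The authors' series table has 21874 entries and a smallest value of 50.01. It holds 21869 of the 21873 entries with an intensity of 50 or more on all 6 arrays in the per-sample values, and 108 of its entries differ from those values by more than 0.001 on the log2 scale. The same value of 50 was used as a floor. Where an entry lay under it on every array of 1 group, the change is given as a bound, the bright group's mean against the higher of the floor and the entry's own value. The negative controls had median intensities of 28.5 to 32.5, and 60.6% to 61.6% of the entries reached 50. The number of arrays limits the precision. The median within-group SD of an entry was 0.47 on the log2 scale, over all entries. For 141 control entries printed several times on an array, the median SD was 0.18 between copies on an array and 0.23 between samples.

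Genes were named by a rule fixed before the data were examined. It takes every entry of BCR and ABL1, and BGLT3. It takes up to 12 rises and 12 falls past the threshold with no overlap between the groups and a mean in the higher group above the median of all entries, passing over provisional symbols, Y-linked genes and genes of X inactivation. From each list it takes up to 4 members past the threshold over all entries, or the 2 with the largest change. Other genes named in the text were chosen after their values were seen, mostly among members that passed when adjusted over their list alone. BCR and BGLT3 matched no entry, and some genes the rule takes are not reported here.

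Simulated arrays took the measured means of the 49387 entries, and for each entry a spread drawn at random from the distribution of spreads that limma fitted to them. On these the test recovered 0 of 50 entries changed by 1 on the log2 scale, 5 of 50 changed by 2, 35 of 50 changed by 3 and 45 of 50 changed by 4, with 2 false calls. The list test, on 15696 simulated genes, called 10 of 10 lists of 25 genes that were shifted by 0.5, and 0 of 100 lists without a shift. In that simulation the genes varied independently of one another.

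Alternatives fixed in advance were leaving out the dimmest 25% of entries, quantile normalization, median centring, the series table, an intensity trend with robust moderation, array weights, a 2-fold minimum, a test against a 1.2-fold change, a block for the replicate number, 1 value per gene, leaving out each sample, camera with an estimated correlation, and fry, which asks whether a list's genes move, on balance, one way. A filter at the floor of 50, alone and with the trend and robust moderation, was added after seeing the data, as were 10 further marker lists.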

Results

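Transcript levels were measured on 6 arrays of K562 cells, 3 from cells given an shRNA against BCR-ABL and 3 from cells given an shRNA against luciferase. The arrays carry mRNA entries and a large set of entries for other transcripts, 49387 in all. The comparison asks which transcripts differ when the BCR-ABL fusion kinase of this leukaemia line is targeted, in a study concerned with a long non-coding RNA that acts as a tumour suppressor. Between 29940 and 30438 entries reached an intensity of 50 on an array, and array pairs correlated at 0.903 to 0.957 over all entries.

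ABL1, the kinase partner of the fusion, did not differ between the groups by the test. Its brighter entry (NM_007313) read 13.60 ± 0.03 on the log2 scale (SD, n = 3) in BCR-ABL shRNA samples and 13.83 ± 0.16 in luciferase samples, a difference of -0.23 with a standard error of 0.26 (limma, adjusted p = 0.783 over all entries and 0.805 over the ABL1 entries alone). The other (NM_005157) read 12.23 ± 0.26 and 12.30 ± 0.26, a difference of -0.07 with a standard error of 0.29 (adjusted p = 0.952, and 0.816 over these entries alone). By replicate, the brighter entry read 13.57, 13.63 and 13.59 under BCR-ABL shRNA and 13.97, 13.84 and 13.66 under luciferase shRNA. The dimmer one read 12.15, 12.02 and 12.52 against 12.08, 12.58 and 12.23. The target site of the shRNA and the probe positions are not given in the sources used here, and an ABL1 probe also reads the normal ABL1 transcript, so these entries do not measure the depletion of the fusion. BCR was not analysed here.

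With BCR-ABL targeted, lists of red cell maturation genes stood higher by camera at a preset correlation between genes. By that test lists linked to growth factor signalling and markers of other cell types stood lower, the fibroblast and epithelial list furthest, at -1.52. With an estimated correlation 0 of 34 lists passed, and a single entry passed the test over all entries. That entry was OAS1 (NM_002534), an interferon-induced enzyme that makes 2',5'-oligoadenylates in response to double-stranded RNA. It fell from 9.38 ± 0.21 to 5.29 ± 0.20 on the log2 scale (SD, n = 3), lay under an intensity of 50 on all 3 BCR-ABL shRNA arrays, and so was at least 13.3-fold lower (limma, adjusted p = 0.0364). Its entries NM_016816 and NM_001032409 had differences of -2.81 (adjusted p = 0.32) and -3.10 (adjusted p = 0.281) and did not pass. On BCR-ABL shRNA replicates 1, 2 and 3 they read 5.99, 6.40 and 9.17, and 5.03, 5.74 and 8.49, against luciferase means of 10.00 ± 0.73 and 9.52 ± 0.15 (SD, n = 3). At an unadjusted p under 0.05 there were 5410 entries, 2833 higher and 2577 lower, where 2469 would come by chance, and in 17.1% of entries the groups did not overlap, against 10% by chance. Leaving out BCR-ABL shRNA replicate 3 gave 427 entries past the threshold, 28 higher and 399 lower. Among them were 6 of the 13 measured genes of an epithelial core list and 3 of the 8 of a mammary epithelium list, both chosen after seeing the data. GATA3 and FOXA1 of the mammary list were not, with changes of -0.32 and -0.40 with all 6 arrays. Of the lists fixed beforehand the entries held 4 of 18 fibroblast and epithelial, 2 of 19 granulocyte and monocyte and 0 of 16 T and B cell markers. They also held genes of no marker list used here, such as CDH17, KRT20, GPA33, CDX1, GUCY2C and C1QA. No list of intestinal genes was among those used, so the lists neither name nor exclude a tissue, and the source of these transcripts was not tested. Of the 399 lower entries 350 read nearer to the luciferase mean than to the other BCR-ABL shRNA arrays on the array left out. Entries that pass only without an array tend to depart from their group on it, so the selection favours this count. The share over all entries was not computed, and the count does not show by itself that replicate 3 was like the luciferase arrays. Leaving out BCR-ABL shRNA replicate 1 or 2 or luciferase replicate 1, 2 or 3 gave 0 in each case, with adjusted p for OAS1 from 0.133 to 0.342. An intensity trend with robust moderation gave 40 entries, 20 in each direction, and the mean of each gene's entries gave 9 genes.

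Of the 34 gene lists tested, 16 passed camera, 6 higher and 10 lower with BCR-ABL targeted. With a correlation between genes estimated from these arrays, 0 of the 34 passed, so the p from that test stands beside each list. By fry, 7 passed: erythroid markers, globins, ERK output genes, STAT5 targets, NF-kB response genes, CML stem and progenitor genes, and fibroblast and epithelial markers. The other lists that passed camera did not pass fry.

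Erythroid genes formed the group with the largest rise. The 21 measured erythroid markers rose by a mean of 1.57 on the log2 scale (camera adjusted p = 2.18e-13; adjusted p = 0.265 with an estimated correlation), and 17 of them rose adjusted over the list alone, against 0 over all entries. SLC4A1, the band 3 anion exchanger of the red cell membrane, went from 7.34 ± 0.93 to 12.21 ± 0.73 (SD, n = 3), a change of 4.87 with a standard error of 0.56 (adjusted p = 0.109 over all entries). EPB42, the membrane protein 4.2 that binds band 3, rose by 4.48 with a standard error of 0.59, and AHSP, the chaperone of free alpha globin, by 4.39 with a standard error of 0.58. CA1, a carbonic anhydrase of red cells, rose by 2.37 and KEL, the Kell antigen, by 2.24. The list mean stood above the luciferase mean by 1.92, 0.96 and 1.85 in BCR-ABL shRNA replicates 1, 2 and 3. On the same arrays the fibroblast and epithelial list, markers of other cell types, stood at -1.67, -2.001 and -0.88.

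**Figure D1:**
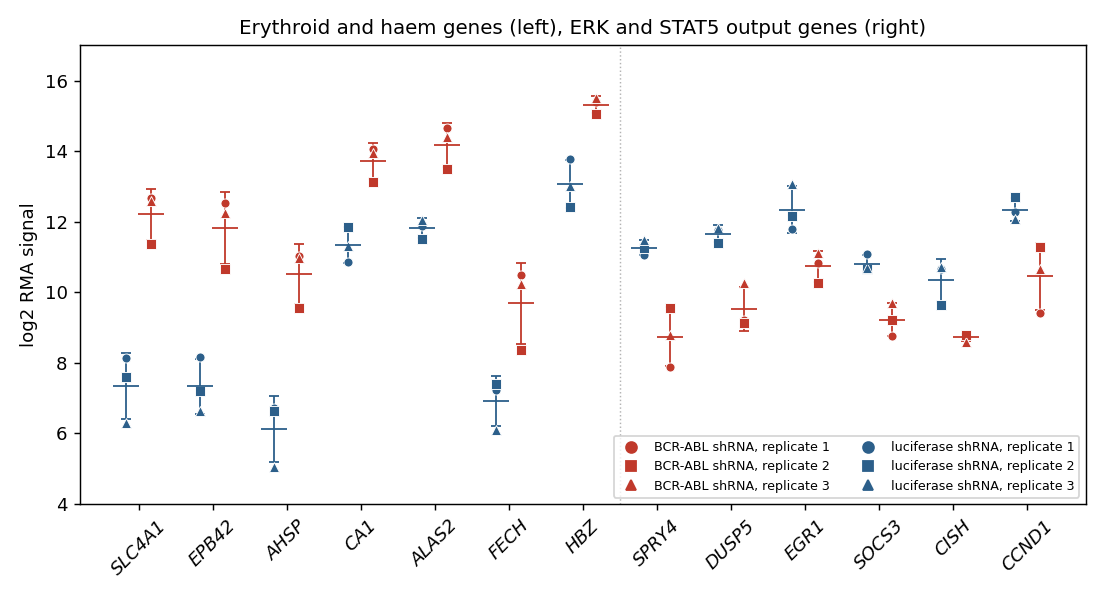
Log2 RMA signal of 13 genes on each of the 6 arrays, with BCR-ABL shRNA in red and luciferase shRNA in blue. Marker shapes give the replicate, the horizontal bars the group mean and the vertical bars the SD (n = 3). SLC4A1 stood at 12.21 against 7.34, and SPRY4 at 8.75 against 11.27.

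The enzymes of haem synthesis moved with them. The 17 measured members rose by a mean of 0.75 (camera adjusted p = 6.06e-05; adjusted p = 0.401 with an estimated correlation), and adjusted over the list alone 8 rose and 1 fell, against 0 over all entries. By BCR-ABL shRNA replicate (1, 2 and 3) the list stood at 0.96, 0.32 and 0.96 against the luciferase mean, where the fibroblast and epithelial list stood at -1.67, -2.001 and -0.88. FECH, which inserts iron into protoporphyrin, rose by 2.78 with a standard error of 0.62, and ALAS2, the erythroid enzyme of the first step, by 2.36 with a standard error of 0.38. PPOX, ALAD and CPOX rose by 1.60, 1.49 and 1.44. The member that fell was HMOX1, which degrades haem, at -2.09. The list of control genes, which shares a member with this one, had a mean change of 0.37 over 13 measured members and did not pass (adjusted p = 0.0664).

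The 8 measured globins rose by a mean of 0.96 (camera adjusted p = 0.000495; adjusted p = 0.25 with an estimated correlation), 3 of them adjusted over the list alone and 0 over all entries. In BCR-ABL shRNA replicates 1, 2 and 3 the list stood at 1.16, 0.42 and 1.28 against the luciferase mean, lowest in replicate 2. The fibroblast and epithelial list was also lowest there, at -2.001. HBZ, the embryonic alpha-like chain, went from 13.07 ± 0.67 to 15.31 ± 0.24, and HBD, the delta chain, from 6.30 ± 0.63 to 8.86 ± 1.502. HBA1 rose by 0.87, but its sequence is nearly that of HBA2, so its probes may not part them. Erythroid transcription factors (12 measured) rose by a mean of 0.74 (camera adjusted p = 6.19e-06; adjusted p = 0.324 with an estimated correlation), and by 0.92, 0.61 and 0.70 in the 3 replicates. Adjusted over the list alone 1 rose, GFI1B, a repressor needed for red cell and platelet precursors, by 1.66, and over all entries 0. TAL1, which acts with GATA1, had a change of 0.98 and did not pass. In the megakaryocyte list, the platelet lineage, the mean change of 23 members was 0.06 and the list did not pass (adjusted p = 0.94). Adjusted over that list alone TUBB1, the platelet beta-tubulin, rose by 3.35 and VWF fell by 1.77, and over all entries 0 passed.

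Proliferation genes stood slightly higher. The 34 measured genes of DNA replication and the G1/S transition rose by a mean of 0.40 (camera adjusted p = 4.66e-06; adjusted p = 0.324 with an estimated correlation), and the 35 mitosis genes by a mean of 0.31 (camera adjusted p = 9.51e-05; adjusted p = 0.401 with an estimated correlation). By replicate (1, 2 and 3) the lists stood at 0.47, 0.36 and 0.38 and at 0.44, 0.13 and 0.36 against the luciferase mean, where the fibroblast and epithelial list stood at -1.67, -2.001 and -0.88. In both lists 33 members had a positive change, and 0 passed either adjusted over the list alone or over all entries. The list of control genes, which did not pass, had a mean change of 0.37, of like size. Its median change was 0.14, against 0.44 and 0.30 for the 2 proliferation lists. MKI67, the Ki-67 proliferation antigen, had a change of 1.07, GINS3, a part of the replicative helicase, 0.89, and MCM6, another part of it, 0.89. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, fell by 1.45 adjusted over the CDK inhibitor list alone, a list of 10 members that did not pass (mean change 0.18, adjusted p = 0.199). CDKN1C, of the same list, had a change of 1.199 and did not pass.

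The lists of ERK output genes and STAT5 targets stood lower. ERK output genes, transcribed when the RAS-MAP kinase cascade is active, fell by a mean of 1.12 over 24 measured members (camera gave a mean change of -1.12 with adjusted p = 7.86e-09; adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone 9 fell, and over all entries 0. SPRY4, a feedback inhibitor of the cascade, went from 11.27 ± 0.21 to 8.75 ± 0.85 (SD, n = 3), DUSP5, a phosphatase that inactivates ERK, from 11.66 ± 0.24 to 9.53 ± 0.63, and the early growth response factor EGR1 fell by 1.60. CCND1, cyclin D1, which stands in the ERK and the STAT5 list, fell by 1.90. STAT5 targets (16 measured) had a mean change of -0.64 (camera adjusted p = 0.00285; adjusted p = 0.25 with an estimated correlation). Adjusted over that list alone 4 fell, among them CISH at -1.62 and SOCS3 at -1.59, both feedback inhibitors of JAK-STAT signalling, and over all entries 0. For ERK output the means relative to luciferase were -1.55, -1.03 and -0.79 in BCR-ABL shRNA replicates 1, 2 and 3, and for STAT5 targets -0.67, -0.68 and -0.56. On the same arrays the fibroblast and epithelial list stood at -1.67, -2.001 and -0.88. Whether lower signalling in K562 cells or other RNA on the luciferase arrays accounts for the lower ERK and STAT5 lists was not tested.

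**Figure D2:**
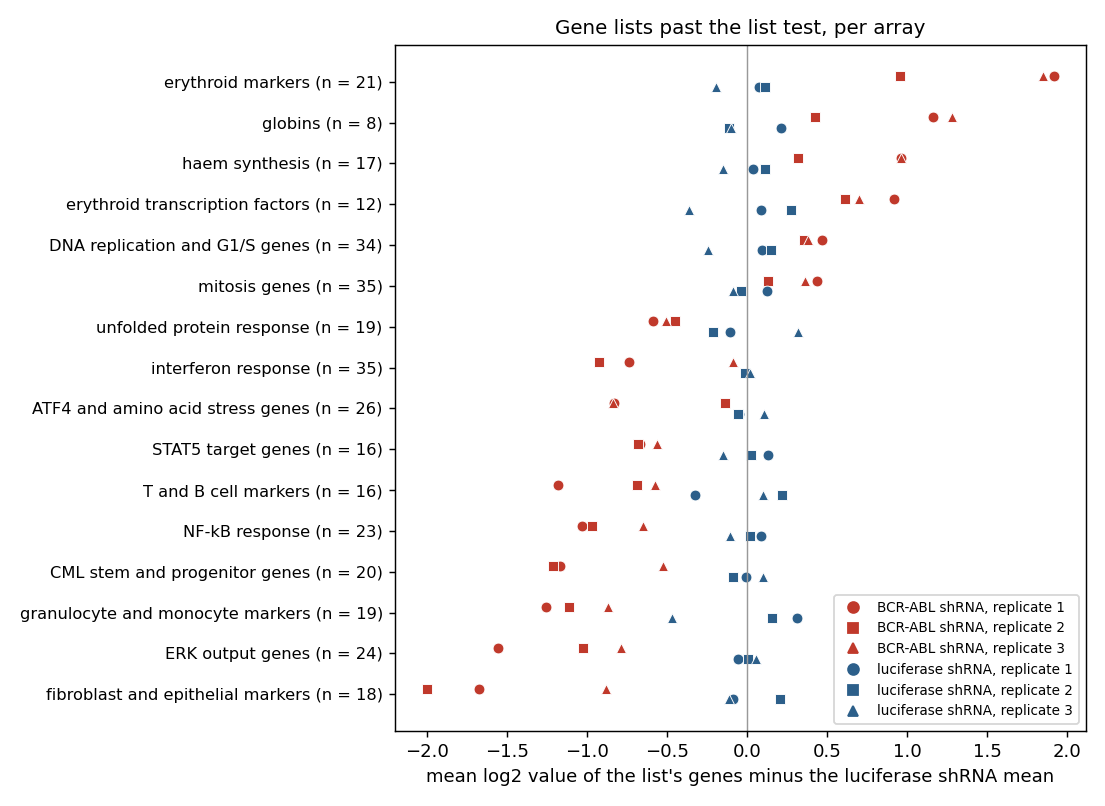
Mean log2 value of the measured genes of each list that passed camera, per array and relative to the mean of the luciferase shRNA arrays. BCR-ABL shRNA arrays are red, luciferase arrays blue, and marker shapes give the replicate. In the interferon list BCR-ABL shRNA replicate 3 stood at -0.09, near the luciferase arrays, and replicates 1 and 2 at -0.74 and -0.93.

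Markers of other cell types were lower with BCR-ABL targeted. The fibroblast and epithelial list (18 measured) had a mean change of -1.52 (camera adjusted p = 7.86e-09; adjusted p = 0.25 with an estimated correlation), and 12 members fell adjusted over the list alone, against 0 over all entries. COL1A1 and COL1A2, the chains of type I collagen, had changes of -2.74 and -2.93, DCN, the matrix proteoglycan decorin, -2.27, and CDH1, E-cadherin, -3.27. E-cadherin read 6.06, 5.06 and 10.06 on BCR-ABL shRNA replicates 1, 2 and 3 and 10.43, 9.81 and 10.76 on the luciferase arrays. Granulocyte and monocyte markers (19 measured) had a mean change of -1.08 (camera adjusted p = 1.43e-05; adjusted p = 0.268 with an estimated correlation), with 5 falling adjusted over the list alone and 0 over all entries, among them S100A9 at -3.21 and TYROBP at -3.10. T and B cell markers (16 measured) had a mean change of -0.81 (camera adjusted p = 0.00188; adjusted p = 0.268 with an estimated correlation). Adjusted over that list alone 5 fell, among them CD3D, a chain of the T cell receptor complex, at -2.82, and 1 rose, IGLL1, at 1.498, against 0 over all entries. An epithelial core list chosen after seeing the data had mean levels of 6.68, 6.67 and 9.56 on BCR-ABL shRNA replicates 1, 2 and 3, and of 9.45, 9.66 and 10.16 on the luciferase arrays.

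Inflammatory and stress programmes were lower on the same arrays. NF-kB response genes (23 measured) had a mean change of -0.88 (camera adjusted p = 1.14e-05; adjusted p = 0.25 with an estimated correlation), and 10 fell adjusted over the list alone, against 0 over all entries, among them BCL3 at -2.32, CCL20 at -2.52 and TNFAIP3 at -1.29. The list of CML stem and progenitor genes (20 measured) had a mean change of -0.97 (camera adjusted p = 0.00158; adjusted p = 0.25 with an estimated correlation) with 4 falling adjusted over the list alone, CD34 at -2.70, HOXA10 at -2.62, CD33 at -1.69 and GATA2 at -1.43, and 0 over all entries. In the series table, which leaves out the dimmer entries, that list did not pass (adjusted p = 0.143). PROM1, the antigen CD133, had a change of -2.82 and did not pass. Interferon response genes (35 measured) had a mean change of -0.58 (camera adjusted p = 0.0087; adjusted p = 0.401 with an estimated correlation). Adjusted over that list alone 2 fell, PSMB9 at -2.07 and TAP1 at -1.63, both of the antigen presentation pathway, and over all entries 0. These counts use the brightest entry of each gene, which for OAS1, a member of this list, is not the entry that passed over all entries. PSMB8, another subunit of the immunoproteasome, had a change of -2.83 and did not pass. Without BCR-ABL shRNA replicate 2 the interferon list no longer passed, with adjusted p = 0.0805. In these replicates (1, 2 and 3) the fibroblast and epithelial list stood at -1.67, -2.001 and -0.88, the NF-kB list at -1.03, -0.97 and -0.65 and the CML stem and progenitor list at -1.17, -1.21 and -0.53. CCL20 read 7.68, 6.78 and 10.39 in them, and BCL3 7.02, 7.33 and 9.45. PSMB8 read 7.39, 6.79 and 10.21, and PROM1 6.29, 5.99 and 9.34. Their lowest luciferase readings were 10.61, 10.12, 10.51 and 9.36, so replicate 3 lay nearer to the luciferase arrays than replicates 1 and 2. CD34 went otherwise, at 5.66, 5.11 and 6.42 against at least 7.17 on the luciferase arrays.

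ATF4 and amino acid stress genes (26 measured) had a mean change of -0.60 (camera adjusted p = 9.51e-05; adjusted p = 0.454 with an estimated correlation), and unfolded protein response genes (19 measured) of -0.51 (camera adjusted p = 0.000229; adjusted p = 0.384 with an estimated correlation). In each list 0 members passed adjusted over the list alone or over all entries. NUPR1 had a change of -2.79, TRIB3, a pseudokinase induced by ATF4, of -2.02, HSPA5, the chaperone BiP, of -1.16 and MANF of -1.10. For ATF4 genes the replicates stood at -0.83, -0.13 and -0.84 against the luciferase mean. The fibroblast and epithelial list stood lowest in replicate 2, at -2.001.

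The remaining 18 lists did not pass camera. Mean changes were 0.28 for replication-dependent histones (adjusted p = 0.0635), -0.25 for glycolysis (0.112), 0.13 for the proteasome (0.115), -0.40 for FOXO targets (0.115), -0.24 for pro-apoptotic genes (0.27), 0.12 for cholesterol synthesis (0.27), -0.29 for anti-apoptotic genes (0.328), 0.07 for ribosomal proteins (0.57), 0.03 for autophagy and lysosome genes (0.577) and 0.09 for heat shock genes (0.593). They were -0.18 for BCR-ABL adaptors and kinases (0.647), -0.03 for MYC targets (0.902), -0.11 for tumour suppressors (0.922), -0.05 for p53 targets (0.971) and 0.01 for oxidative phosphorylation (0.971). Mean, median and test differed in sign for heat shock genes, oxidative phosphorylation, tumour suppressors and p53 targets. Among their members, the glucose transporters SLC2A1 and SLC2A3 had changes of 2.43 and -1.80, SRC, a kinase, -2.24, PTPN6, the phosphatase SHP-1, -2.14 and INSR, the insulin receptor, -2.04. Adjusted over the list alone, INSR, ERBB3 and CDKN1A fell and CITED2 rose among FOXO targets, and PHLDA3 and CDKN1A fell and MDM2 rose among p53 targets, while SLC2A1, SLC2A3, SRC and PTPN6 did not pass in these lists.

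At an unadjusted p under 0.05, ASLNC entries were more often higher than lower and RefSeq mRNA entries more often lower than higher, while the median change over all entries of a class was 0.13 for ASLNC and 0.010 for RefSeq. Of the 18534 ASLNC entries, 1245 were higher and 528 lower with BCR-ABL targeted at an unadjusted p under 0.05, and 0 passed the adjusted test. Of the 20447 RefSeq entries, 1008 were higher and 1722 lower at that p, and 1 passed. After median centring these counts were 1134 and 558 for ASLNC and 931 and 1804 for RefSeq, and the medians 0.10 and -0.013. HMlincRNA entries numbered 214, with 5 higher and 1 lower at that p and 0 past the adjusted test.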

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

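The filter at an intensity of 50 and its pairing with the trend were chosen after seeing the data. The count of entries past the threshold, 1 as reported, was 0 in the series table, 0 with 1 value per gene from the brightest entry, 9 with the mean of a gene's entries, 40 with an intensity trend and robust moderation, 65 with that and the filter at 50, and 0 to 427 on leaving out 1 sample. The 427 came without BCR-ABL shRNA replicate 3 and included OAS1. Each of the other 5 samples left out gave 0 by limma, with 3329 to 5903 entries at an unadjusted p under 0.05. The trend and the robust moderation were changed together, and the cause of these differences was not tested. The values gave no sign that the replicate numbers pair the samples: same-numbered samples had deviations from their group means that correlated at 0.01, -0.09 and 0.00. A shared infection or day is not excluded by this, since other differences between single arrays can hide it. A replicate block, which uses up degrees of freedom, gave 0 entries (adjusted p for OAS1 of 0.258, 4904 entries at an unadjusted p under 0.05) and 16 lists.

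Of the gene lists, 16 passed as reported, 0 with an estimated correlation, 7 by fry and 16 to 18 on leaving out 1 sample. Values near 0 changed sign. ABL1 NM_005157 turned from -0.07 to 0.021 with array weights and ranged from -0.22 to 0.072 on leaving out 1 sample, with the sign reversed without BCR-ABL shRNA replicate 2 or luciferase replicate 2. Lists that did not pass as reported turned too. On leaving out 1 sample, MYC targets ranged from -0.20 to 0.11, autophagy and lysosome genes from -0.025 to 0.12, megakaryocyte markers from -0.051 to 0.18, oxidative phosphorylation from -0.030 to 0.046 and tumour suppressors from -0.22 to 0.0015. Oxidative phosphorylation turned to -0.013 with median centring and -0.018 with quantile normalization, and p53 targets to 0.089 in the series table. The cause was not tested. MYC targets passed without luciferase replicate 3 (adjusted p = 0.0428), FOXO targets without BCR-ABL shRNA replicate 3 (0.046) or luciferase replicate 2 (0.046), control genes without BCR-ABL shRNA replicate 2 (0.0442), and histones without BCR-ABL shRNA replicate 2 (0.0347) or luciferase replicate 3 (0.000158). Glycolysis passed in the series table (0.0195), and histones with the mean of a gene's entries (0.0448). The lists were not tested with array weights, with the trend and robust moderation, or with the 2-fold minimum and the test against a 1.2-fold change. Of the 16 lists called, 14 passed under every alternative run for lists but the estimated correlation and fry. The exceptions were the interferon list and the CML stem and progenitor list. Each of the 16 kept its direction under all alternatives run for lists. Intensity over background limits what can be read: 38.9% of values lay under 50.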

Other observations

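Some members of lists written after the data had been seen stood lower with BCR-ABL targeted. In a mammary epithelium list of 8 measured genes the trefoil factors TFF1 and TFF3 and the disulfide isomerase AGR2 had log2 changes of -5.23, -4.03 and -5.29, with adjusted p of 0.228, 0.234 and 0.291 over all entries, and 5 of the 8 fell adjusted over the list alone. AGR2 read 5.24, 4.44 and 10.59 on BCR-ABL shRNA replicates 1, 2 and 3, and 11.59, 11.77 and 12.77 on the luciferase arrays. GATA3 and FOXA1 of that list had changes of -0.32 and -0.40 and did not pass. Of the 8 measured plasma cell genes 3 fell adjusted over the list alone, among them CD27 at -2.04 and PRDM1 at -1.34, with a list mean of -1.32. In a list of 9 hepatic transcription factors 2 fell, FOXA2 at -1.71 and PROX1 at -2.02, with a list mean of -0.77. Melanocyte, embryonal carcinoma and neural lists had mean changes of -0.25, -0.27 and -0.06 and 0 members past the threshold. Of the mammary epithelium, plasma cell and hepatic transcription factor lists, 1 listed gene each also stands in a list fixed beforehand. The lists in this part were written after the data had been seen but before their own values were, while the tests of ALB, APOA1 and TTR, of the marker lists in the series table and of dilution by 1 factor were chosen only after their results were seen.

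Markers of other cell types were lower on the BCR-ABL shRNA arrays. Signals under an intensity of 50 do not account for the whole: in the series table, whose smallest value is 50.01, the fibroblast and epithelial, granulocyte and monocyte, and T and B cell lists kept mean changes of -1.56, -1.45 and -0.97 over 9, 7 and 7 members and passed camera at the preset correlation. On all entries these lists did not pass with an estimated correlation, and the granulocyte and monocyte and T and B cell lists did not pass fry (adjusted p = 0.0576 and 0.0619). A shift by signal, from background or normalization of dim entries, would move markers and other entries of like signal alike. The 14972 RefSeq entries in the signal range of the called markers had a median change of 0.013 with quartiles of -0.41 and 0.35. The lists had means over all members of -1.52, -1.08 and -0.81, so they fell further than most entries in that range. The range takes in most of the 20447 RefSeq entries, whose median RMA holds near 0. A shift of the dim entries alone is therefore not decided by this comparison. RNA of epithelial cells on the luciferase arrays is a candidate explanation, since the epithelial core list had a mean change of -2.12 and 13 of its 13 measured genes reached an intensity of 50 on all 3 luciferase arrays, against 7 on all 3 BCR-ABL shRNA arrays, among them EPCAM at 12.74 and 13.05 in the groups (1 listed gene also stands in a list fixed beforehand). It stays open. Of 6 further lineages 2 were lower by over 0.5, plasma cell and mammary epithelium, but that test asked about other cells in general and does not decide on epithelial ones. Of the genes that K562 cells have lost at 9p21 1 was measured, CDKN2A, too few to decide, with changes of 0.12 and -0.72 for its 2 entries, the first at levels of 6.07 to 7.07, above an intensity of 50 on all 6 arrays. BCR-ABL shRNA replicate 3 lay at the luciferase level for the core list, at 9.56, and replicates 1 and 2 at 6.68 and 6.67, so the core list does not follow the groups alone. Levels of the core list thus differed between the BCR-ABL shRNA samples. Whether RNA of epithelial cells was the source was not tested, nor was an effect of the shRNA on these genes in K562 cells. The core list holds epithelial genes, so epithelial RNA is a candidate for that part of the pattern only. On BCR-ABL shRNA replicates 1, 2 and 3 the granulocyte and monocyte list stood at -1.25, -1.11 and -0.87 against the luciferase mean. The T and B cell list stood at -1.18, -0.69 and -0.58. On replicate 3, a single array, both lay under all 3 luciferase arrays, and their source was not tested.

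Erythroid and haem genes were higher on the BCR-ABL shRNA arrays. A single array does not account for it, since the lowest mean change of the erythroid list without 1 array was 1.40, against 1.57 with all, and the list passed camera each time. Dilution by 1 factor as the whole cause would move the erythroid markers alike if the other RNA carried none of them and the arrays read each change in full. Of the 17 markers at an intensity of 50 or more on all 6 arrays, 5 lay more than 3 standard errors from their weighted mean change of 1.39. SLC4A1 at 4.87 and RHAG at 0.46 were among them. The 2 conditions were not tested, so these values argue only against a factor shared by all of these markers. Dilution of K562 RNA by other RNA on the luciferase arrays stays open otherwise: 17794 RefSeq entries of like signal had a median change of 0.0072, but genes that the other RNA also carries need not rise, and which these are was not tested, nor was dilution for the proliferation genes. An effect of the BCR-ABL shRNA, the biological difference in the design, may account for these values and is a hypothesis beside it, found and tested on the same data, and batches of hybridization are not given in the sources used here.

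Most hepatocyte genes were lowest on luciferase replicate 2, 13 of the 14 measured and 4 of them by more than 2 on the log2 scale, though TF read 10.17 and RBP4 8.61 there. FGA read 5.15 on that array and at least 9.15 on the other 5, and FGB 4.35 against at least 7.96, while ALB was dim throughout, at most 7.33. In a second liver list 12 of 24 genes were lowest there, 4 by more than 2, among them HP at 6.67 against at least 10.52. FABP1, at 11.77 there, was not. It read 8.14, 7.19 and 11.79 on BCR-ABL shRNA replicates 1, 2 and 3, and 11.57 and 11.48 on luciferase replicates 1 and 3. It was thus low on the arrays where the epithelial core list was low. On luciferase replicate 2 the mean of the second list lay under the lowest other array by a difference of -0.93. That is between the bounds set for liver-type transcripts on 5 arrays. Of ALB, APOA1 and TTR, 1 lay far under the hepatocyte median on at least 4 of the 5, so hepatocytes or hepatoma cells as a possible source stay open. Between the groups the lists had mean changes of 0.35 and 0.12, and no biological explanation was tested, since the labels give that sample no treatment of its own.

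Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 1 entry past the threshold, and the highest of the others was 0. For gene lists the real split gave 16 and the highest of the others 11. In both cases the 1 split of 10 with as many was the real one itself. With 10 splits the share is never under 0.1, so the splits are too few for a share under 0.05.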
